A study of Mus musculus with 2 samples.

How the data were processed

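Gene expression was measured in GIF-5, a mouse gastric epithelial cell line with both Runx3 and p53 deleted, per the labels. A phycoerythrin-coupled antibody against CD133 was used to separate a suspension of the cultured cells by flow cytometry into CD133-positive and CD133-negative fractions, and total RNA was isolated with Trizol, amplified and labelled, per the labels. On each of 2 Agilent arrays, Cy3-labelled RNA of CD133-positive cells was hybridised together with Cy5-labelled RNA of CD133-negative cells. The labels name the arrays biological replicates 1 and 2. Both arrays had the same dye orientation, so a dye effect cannot be separated from the fraction. Both lay on 1 slide with the same scan time per the file headers, so there was no scan batch to compare.

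The deposited files hold 45018 spots per array. Spot and local background brightness are given as intensity, unnormalised, as read by Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited processed signals are also an intensity. They were background-subtracted, detrended over the array and dye-normalised by that program, with dim spots replaced by a surrogate above 0, per the file headers. The deposited log10 ratio is that of red over green processed signals, so of CD133-negative over CD133-positive cells. The deposited p-value of each spot comes from the technical error model of the program for a single array, per the file headers. The value table of the series held the same log10 ratios in all 45018 spots of both arrays, with a median of 0, and 27.2% and 27.3% of spots at 0 on arrays 1 and 2. No spot was saturated. In Cy3, 23694 and 23498 spots were well above background on arrays 1 and 2 by the flag of the program, and in Cy5, 25213 and 24648 were. The number of arrays limits the precision.

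Spot intensities were background-corrected by normexp with an offset of 50 and normalised within each array by loess, with control spots at weight 0. Ratios were expressed as log2 of CD133-positive over CD133-negative cells, and spots of the same probe were averaged. A probe was tested if it was well above background in Cy3 on both arrays or in Cy5 on both arrays and carried no non-uniformity or population outlier flag. Of 41174 non-control probes, 22951 were named through their accession and 9768 through their symbol or a synonym in a RefSeq gene table (GRCm38.p6, used for names only), and 8455 kept the name in the files. A gene was represented by its tested probe with the highest mean log2 intensity. This gave 23173 tested probes and 15267 tested genes. Among 86 called genes with more than 1 tested probe, 1 had a probe of opposite mean direction (Hip1, named after its values were seen).

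Differences were tested with limma 3.58.1 in R 4.3.3 (a fit of the mean log2 ratio, then empirical Bayes moderation of the variance), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each array compared the fractions directly and was 1 replicate. The fit had 1 residual degree of freedom per gene, and moderation added 2.87 prior degrees of freedom. Standard errors are the moderated ones. Genes at least 2-fold changed in the same direction on both arrays were also counted, which needs no variance estimate.

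Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with adjustment over the 27 lists that had at least 5 tested genes. The lists were stem and progenitor markers, gastric lineage, intestinal lineage, epithelial, and mesenchymal and EMT (epithelial-mesenchymal transition) markers, Wnt targets, TGF-beta and BMP targets, Notch pathway, Hedgehog pathway, cell cycle, p53 targets, drug transport and detoxification, interferon response, NF-kB and inflammatory genes, immediate-early and heat-shock genes, hypoxia and glycolysis, unfolded protein and amino acid response, cholesterol synthesis, growth factor signalling, and extracellular matrix and adhesion. Blood cell, endothelial, and fibroblast and muscle markers stood for other cell types. Housekeeping, ribosomal protein, mitochondrial respiratory chain and histone genes completed them. Some genes are in more than 1 list. The main tests, the lists and the rule for named genes were fixed before the data were examined. When the listed names were matched to the probes, a few were left out. Si, meant as sucrase-isomaltase, was dropped from the intestinal list because the name resolved to Pmel. Emc8 and Dmac2l, matched by an old name, were dropped from the respiratory chain list.

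By that rule, the named genes were Prom1, Runx3 and Trp53, then the 12 highest and 12 lowest mean log2 ratios among called genes with a named symbol and the same direction on both arrays. From each list it took up to 4 members with the largest mean log2 ratio in size and the same direction on both arrays, at most 2 where the list was not called. Not every gene the rule picked is printed. Other list members are named where a count of 5 or fewer is spelled out, and these were chosen after their values were seen. Where the probe of a gene was not well above background in CD133-negative cells on either array, the fold is a lower bound, written "at least". It was computed from channel levels after loess and quantile normalisation of the mean intensities between arrays, with the CD133-negative level raised to the lowest level well above background in that channel.

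The test was checked on simulated log2 ratios of 15267 genes with 200 changed ones. It called 2.99% of those simulated at a log2 size of 1, 71.6% at 2 and 97.0% at 4. Of its 122 calls, 8 were genes simulated without a change. The simulated genes were independent, with variances drawn from the prior fitted to these data, so these rates need not hold for the measured genes. Alternatives were tried for the background correction, the normalisation, the deposited ratios in place of the intensities, the filters on dim, outlying and saturated spots, the choice of probe, the variance model, the gene test, the list test and the size threshold. Each array was also left out in turn, and the 4 channels were taken as separate samples.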

Results

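The series compared CD133-positive with CD133-negative cells of GIF-5, a mouse gastric epithelial line without Runx3 and p53. CD133, encoded by Prom1, is a membrane glycoprotein used as a marker of stem-like cells in several tissues. There was 1 comparison with 2 arrays, each holding both fractions. The labels call the arrays biological replicates but do not say whether they come from separate cultures and sorts, so what the spread between them covers is not known. Values are log2 ratios of CD133-positive over CD133-negative cells, given as the mean of both arrays ± SE (n = 2), and adjusted p-values of genes are from limma. A dye effect on a gene cannot be separated from the fraction, since CD133-positive RNA was in Cy3 on both arrays.

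Prom1, the sorted marker, was higher in CD133-positive cells by 3.78 ± 0.14, with 3.83 on array 1 and 3.73 on array 2 (limma adjusted p = 0.0095). Its probe was not well above background in CD133-negative cells on either array, so the difference was at least 3.58 on the log2 scale. A second Prom1 probe, also not well above background in CD133-negative cells, gave at least 3.02. Since the cells were sorted on CD133, this value checks the labels and the dye direction and is no finding. The ratio was 0.05 ± 0.14 for the tested probe of Runx3 and -0.05 ± 0.14 for that of Trp53, and the sign of both changed with the scaling. Both probes were well above background in both fractions. Where they lie relative to the deleted parts of these genes is not known, so they do not check the deletions.

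The ratios of 10 spiked-in control RNAs ran from 3.30 to -2.53 on array 1 and from 3.02 to -2.80 on array 2. All 10 were lower on array 2, by 0.23 to 0.42 with a median of 0.37. The genes did not share this offset after loess, which centres them, and whether it applies to them is not known. Over all tested genes the Pearson r of the log2 ratios of the arrays was 0.771 and Spearman's rho was 0.663, across genes, which are not independent replicates. The ratio had the same direction on both arrays in 72.3% of genes. The SD of the log2 ratios over genes was 0.60 on array 1 and 0.76 on array 2. The median SD of a gene between the arrays was 0.18, while repeated spots of a probe within an array had a median SD of 0.04.

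Of 15267 tested genes, 256 were called, 214 of them higher and 42 lower in CD133-positive cells. All 256 were at least 2-fold changed on both arrays, and the smallest adjusted p was 0.0095. At an unadjusted p under 0.05 there were 1815 higher and 2439 lower genes. By size alone, 382 genes were at least 2-fold higher and 322 at least 2-fold lower on both arrays, and 3 were at least 2-fold changed in opposite directions. Array 2 held more lower genes: 406 were at least 2-fold lower on array 1 and 1208 on array 2, against 563 and 639 at least 2-fold higher.

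The number of calls depended on the variance model. Without moderation limma called 0 genes, with 1506 at an unadjusted p under 0.05, and with an intensity trend in the prior variance it called 837. The share of calls that were higher, 83.6%, depended on the test and on the scaling. It was 59.9% with the intensity trend, 97.0% with treat against a log2 fold of 0.5, and with the 4 channels as separate samples 542 of 1062 calls were higher. With other scalings it was 70.4% without background correction, 72.8% with an offset of 16 and 59.0% after scaling between arrays. After median centring over all probes in place of loess it was 4.79% of 10107 calls, with the median of the tested genes at -0.70 on array 1 and -0.76 on array 2. Relative to the median of all tested genes, none of the 256 called genes changed sign under these scalings or with the deposited processed signals.

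**Figure D1:**
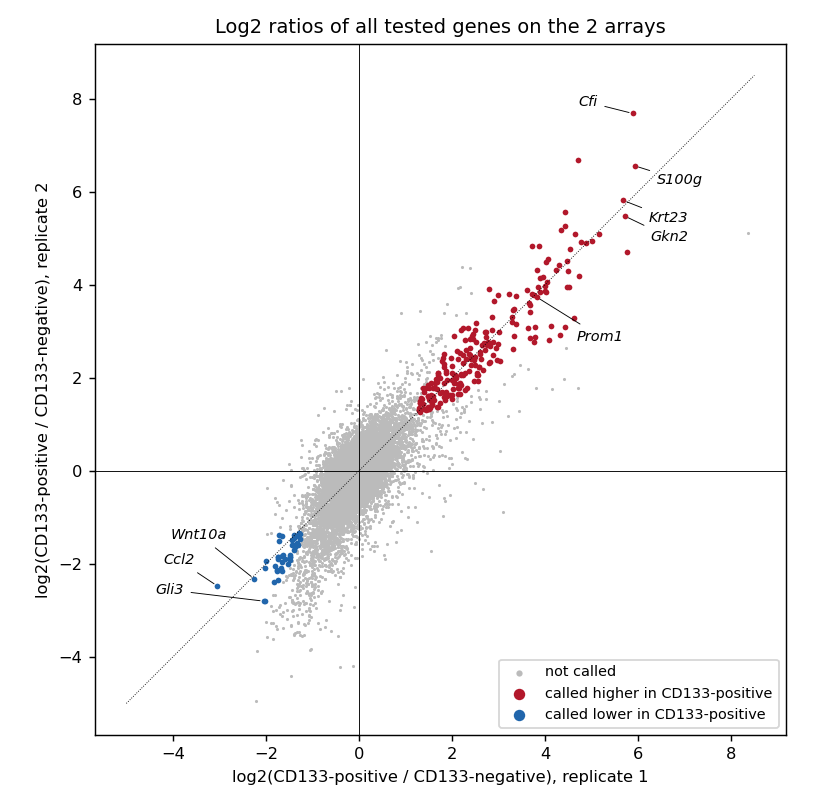
Log2 ratios of CD133-positive over CD133-negative cells of the 15267 tested genes on replicate 1 (x axis) and replicate 2 (y axis), with the 214 genes called higher in red, the 42 called lower in blue, the other genes in grey and a dotted line of equal ratios. Called genes lie near the line, and many uncalled genes lower on both arrays lie below it, with lower ratios on replicate 2.

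The 12 highest called genes had ratios from 6.78 to 4.77, with adjusted p of at most 0.039 in limma. The first was Cfi, complement factor I, at 6.78 ± 0.48. It was followed by S100g, a calcium-binding protein of the intestine (6.24 ± 0.21), the keratin Krt23 (5.75 ± 0.14), the zinc-finger gene Plagl1 (5.70 ± 0.52, well above background in CD133-negative cells on 1 array alone, so its size and rank are uncertain), Gkn2, a gastrokine of stomach surface cells (5.60 ± 0.15), and the antibacterial lectin Reg3g (5.24 ± 0.30). Aspa, Fabp2, Cpm, Slc28a2, Emb and Slc6a15 were between 4.97 and 4.77.

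The 12 lowest called genes had ratios from -2.76 to -1.89, with adjusted p of at most 0.046 in limma. They were the chemokine Ccl2 (-2.76 ± 0.20), the Hedgehog pathway transcription factor Gli3 (-2.42 ± 0.23), the collagen Col7a1 (-2.41 ± 0.24), the ligand Wnt10a (-2.29 ± 0.14) and the filamin Flnc (-2.11 ± 0.20). Cyp1b1, the thrombin receptor F2r, Ildr2, Ahnak, S100a4, Apcdd1 and Zfpm2 were between -2.06 and -1.89.

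**Figure D2:**
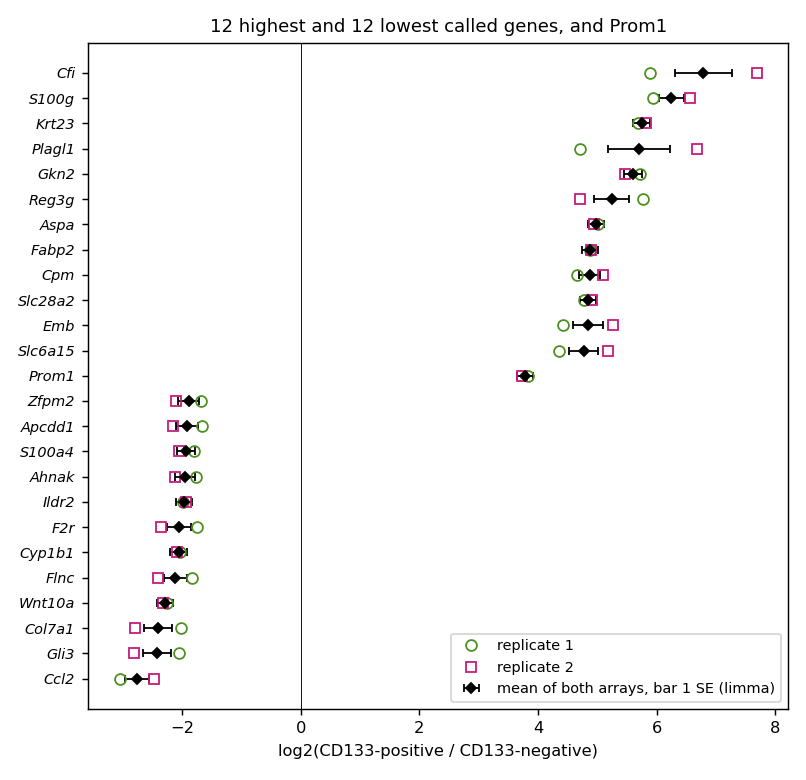
Log2 ratios of CD133-positive over CD133-negative cells (x axis) of the 12 highest and 12 lowest called genes and Prom1 (y axis). Diamonds are the mean of both arrays with a bar of 1 SE from limma, circles replicate 1 and squares replicate 2. The genes run from Cfi at 6.78 to Ccl2 at -2.76.

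Of the 27 gene lists, 13 were called by camera, 7 higher and 6 lower. None of the 13 calls held when the inter-gene correlation was estimated in place of preset, with a camera adjusted p = 0.92 for each. With 1 residual degree of freedom that form had little power, and its smallest unadjusted camera p was 0.12. Losing the calls there therefore decides little. The correlations estimated for the 13 lists ran from -0.05 for NF-kB to 0.78 for hypoxia, against the preset 0.01. Camera compares the genes of a list with other genes, and genes are not independent replicates. Its p-values at the preset correlation, here and below, therefore do not measure the spread between the replicates. Of the 13 lists 1, the NF-kB and inflammatory list, also passed the rotation test fry.

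Gastric lineage markers were higher in CD133-positive cells, with a median of 0.95 over 21 tested members, 1.24 on array 1 and 0.53 on array 2, and 19 members above 0 on both arrays (camera adjusted p = 1.1e-08). Relative to all genes the median was 0.98, and 1.38 with median centring and 1.79 with the deposited processed signals. Of these, 5 rose and none fell. They were Gkn2, the trefoil factor Tff1 (4.40 ± 0.15), the pepsinogen Pga5 (3.77 ± 0.14), the mucin Muc1 (1.78 ± 0.15) and the transcription factor Spdef (1.37 ± 0.14). Of its members, 12 rose adjusted over the list alone. Tff2 was at 2.71 ± 0.35 and did not pass over all genes (limma adjusted p = 0.063). The gastric list held 30 genes, and Cblif, Atp4a, Chga, Gast, Sst and Lipf were among those not tested. These had no probe well above background in either fraction on any array. The list result therefore does not cover them.

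Intestinal lineage markers had a median of 0.49 over 21 members, with 0.61 on array 1 and 0.08 on array 2 (camera adjusted p = 0.0027). The genes that rose were Fabp2 (4.88 ± 0.14), the apolipoprotein Apoa1 (4.23 ± 0.20), the trefoil factor Tff3 (4.21 ± 0.19), the homeobox gene Isx (2.54 ± 0.19) and the galectin Lgals4 (2.41 ± 0.14), and none fell. In this list, 6 rose adjusted over the list alone.

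Stem and progenitor markers did not pass as a list (median 0.08 over 22 members, 0.17 on array 1 and 0.04 on array 2, camera adjusted p = 0.19). Beside Prom1, the receptor gene Kit rose by 4.01 ± 0.15 (limma adjusted p = 0.0095). Adjusted over the list alone, 3 rose and none fell. The stem list held 32 genes, and Lgr5, Sox2, Olfm4 and Pou5f1 were among those not tested. Sox2, Olfm4 and Pou5f1 had no probe well above background in either fraction on any array. Lgr5 had a probe well above background in CD133-positive cells on at least 1 array, and none in CD133-negative cells. For Nanog, also not tested, it was the reverse.

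Mesenchymal and EMT markers had the lowest median of the lists, -1.20 over 21 members, with -0.92 on array 1 and -1.36 on array 2, and 18 members below 0 on both arrays (camera adjusted p = 3.8e-06). S100a4 (-1.93 ± 0.15) and the metalloproteinase Mmp14 (-1.50 ± 0.14) fell, and adjusted over the list alone, 13 fell. Col5a1 (-2.58 ± 0.37) and the EMT transcription factors Twist2 (-2.22 ± 0.34) and Snai2 (-1.79 ± 0.21) did not pass over all genes. Epithelial markers did not pass as a list (camera adjusted p = 0.47), except with median centring over all probes. Their median over 28 members was 0.17 on array 1 and -0.06 on array 2, the median of -0.04 and mean of 0.07 of the ratios averaged over the arrays differed in sign, and the sign of the median relative to all genes changed under 3 scalings. The protease Prss8 (2.36 ± 0.15) and the junction genes Ocln (1.81 ± 0.16) and Tjp3 (1.53 ± 0.16) rose, while the desmosomal gene Dsp, at -2.38 ± 0.33, did not pass. In this list, 7 epithelial markers rose and 7 fell adjusted over the list alone.

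NF-kB and inflammatory genes had a median of -0.95 over 21 members, with -0.89 on array 1 and -0.98 on array 2 (camera adjusted p = 2.8e-05, fry adjusted p = 0.042). The camera call was lost with median centring over all probes. Ccl2, the adaptor Traf1 (-1.80 ± 0.14), the cytokine Il33 (-1.46 ± 0.14) and the complement gene C3 (-1.39 ± 0.14) fell, and the chemokine Ccl20 rose by 1.46 ± 0.14. Vcam1 at 2.28 ± 0.32 and Csf1 at -1.85 ± 0.24 did not pass. Of its members, 2 rose and 14 fell adjusted over the list alone. The NF-kB list held 33 genes, and Tnf, Il1a, Il1b, Il6, Cxcl2 and Nos2 were among those not tested. These had no probe well above background in either fraction on any array.

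Wnt pathway targets had a median of -0.73 over 14 members, with -0.68 on array 1 and -0.81 on array 2 (camera adjusted p = 0.0042), and were not called with either median centring. Apcdd1 fell by 1.91 on the log2 scale, and Ccn4 (-2.39 ± 0.38), Tcf7 (-1.50 ± 0.30) and Sox9 (-1.38 ± 0.36) did not pass. Adjusted over the list alone, 1 rose and 8 fell. The Wnt list held 26 genes, and Axin2, Nkd1, Sp5, Notum, Lef1 and Ephb2 were among those not tested. These had no probe well above background in either fraction on any array. TGF-beta and BMP targets had a median of -0.80 over 23 members, with -0.35 on array 1 and -0.86 on array 2 (camera adjusted p = 0.0042), and were not called with median centring over all probes. The members that passed over all genes were higher, namely the activin-binding Fst (2.44 ± 0.14) and the pseudoreceptor Bambi (2.34 ± 0.14). Id3 (-1.87 ± 0.43) did not pass. Of its members, 2 rose and 11 fell adjusted over the list alone.

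Hedgehog pathway genes did not pass as a list (median -0.42 over 9 members, -0.36 on array 1 and -0.44 on array 2, camera adjusted p = 0.23), but the ligand Ihh rose by 3.88 ± 0.14 and Gli3 fell. In this list, 1 rose and 3 fell adjusted over the list alone. The Hedgehog list held 16 genes, and Gli1, Gli2 and Hhip were among those not tested. These had no probe well above background in either fraction on any array. Notch pathway genes did not pass (median -0.22 over 15 members, -0.10 on array 1 and -0.29 on array 2, camera adjusted p = 0.20), with the ligands Jag2 at -1.99 ± 0.45 and Jag1 at -1.71 ± 0.39. Over all genes none passed, and adjusted over the list alone, 1 rose and 3 fell.

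Extracellular matrix and adhesion genes had a median of -0.63 over 31 members, with -0.67 on array 1 and -0.88 on array 2 (camera adjusted p = 0.010), and were not called with either median centring. The median relative to all genes was -0.60, and -1.17 with the deposited processed signals. The basement membrane genes Col4a1 (2.27 ± 0.15), Lamb1 (2.19 ± 0.14) and Col4a2 (1.87 ± 0.15) rose, and the inhibitor Timp2 fell (-1.55 ± 0.16). Adjusted over the list alone, 5 rose and 17 fell. Spp1 had the lowest ratio, -3.58 ± 0.71, but differed between arrays (-2.22 and -4.95) and did not pass. Col18a1 (-2.43 ± 0.73), Mmp13 (-2.40 ± 0.59) and Nid2, at least 6.38-fold higher, did not pass either.

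Drug transport and detoxification genes had a median of 0.25 over 31 members, with 0.28 on array 1 and 0.24 on array 2 (camera adjusted p = 0.021). Relative to all genes the median was 0.29, and 0.04 under median centring, and the call was lost on ranks, with the filter for both channels and with centring over the tested genes. The carbonyl reductases Cbr3 (2.64 ± 0.15) and Cbr1 (1.71 ± 0.14) and the glutathione transferases Gsta1 (1.77 ± 0.15) and Gsta2 (1.55 ± 0.14) rose, and Cyp1b1 fell (-2.06 ± 0.14). In this list, 11 rose and 3 fell adjusted over the list alone. Gstm2 (2.74 ± 0.45) and Nqo1 (2.05 ± 0.30) did not pass over all genes.

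Hypoxia and glycolysis genes had a median of 0.33 over 35 members (camera adjusted p = 0.0078), but the arrays differed in sign, with 0.71 on array 1 and -0.11 on array 2, and the call was lost with centring over the tested genes. The median relative to all genes was 0.36, and ran from 0.14 with median centring to 0.54 with the processed signals. The secreted glycoprotein gene Stc2 rose by 3.39 ± 0.14, and adjusted over the list alone, 5 rose and none fell. Ankrd37 (2.18 ± 0.53), P4ha2 (1.57 ± 0.20) and Adm (1.31 ± 0.48) did not pass over all genes.

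Ribosomal protein genes had a median of -0.32 over 79 members, with -0.14 on array 1 and -0.49 on array 2 (camera adjusted p = 0.00049). Relative to all genes the median was -0.28, -0.81 with median centring and -0.13 with the deposited processed signals, with which the call was lost, as it was with the value table. Rps23 fell (-1.52 ± 0.14), over all genes and adjusted over the list alone, and Rpl12, Rpl5 and Rpl36a were between -1.41 and -1.17 without passing. Mitochondrial respiratory chain genes had a median of 0.23 over 83 members (camera adjusted p = 3.0e-05), but this was -0.10 relative to all tested genes under median centring, where the list was called lower when centred over all probes and not called when centred over the tested genes. None passed over all genes or adjusted over the list alone; Cox7a1 was at -1.05 ± 0.33, Atp5l at 0.98 ± 0.14, Ndufa5 at 0.87 ± 0.29 and Ndufs3 at 0.84 ± 0.14. Histone genes had a median of 0.28 over 31 members, with 0.10 on array 1 and 0.45 on array 2 (camera adjusted p = 0.0042). Relative to all genes the median was 0.31, and 0.02 under median centring, where the call was lost. None of them passed over all genes or adjusted over the list alone, and H1f3, H2ac15, H2bu2 and H1f2 were between 1.23 and 0.63.

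Unfolded protein and amino acid response genes had a median of 0.21 over 31 members (camera adjusted p = 0.033), which relative to all tested genes was -0.06 under median centring. The call was lost with either median centring, the processed signals, the value table, an offset of 16 and the dimmest probe. Over all genes none passed, and adjusted over the list alone, 1 rose. Xbp1 was at 1.31 ± 0.16, Trib3 at 0.88 ± 0.24, Slc3a2 at -0.66 ± 0.15 and Slc7a5 at -0.65 ± 0.14.

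**Figure D3:**
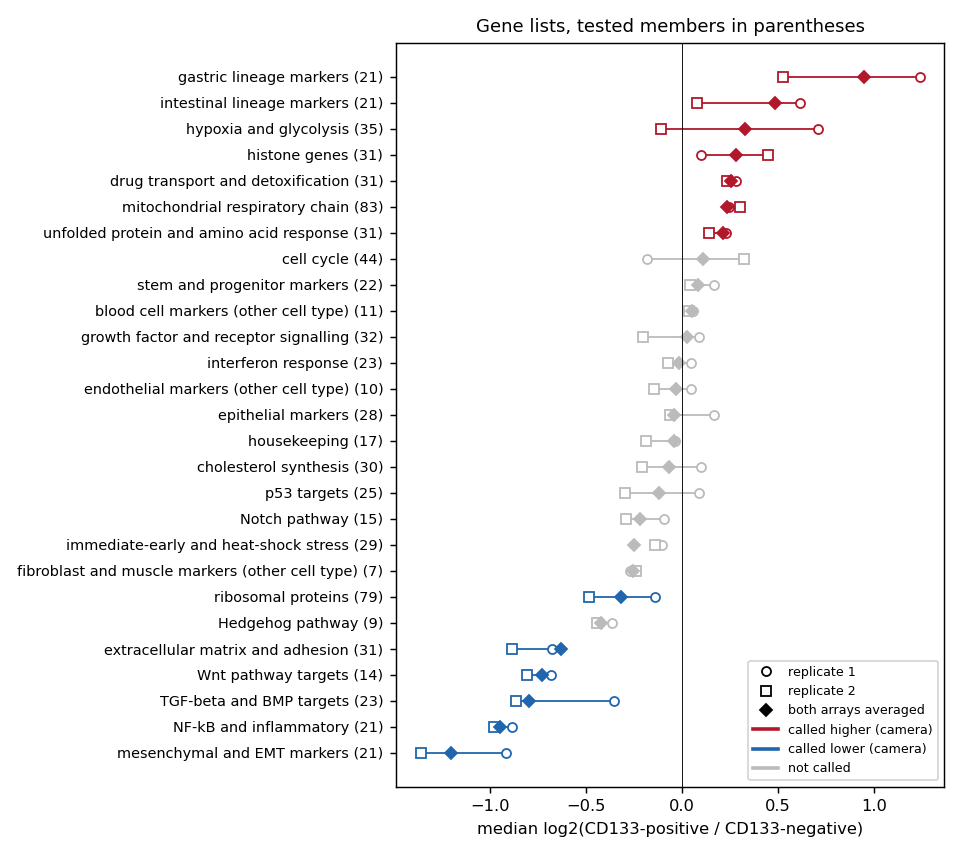
Median log2 ratio of CD133-positive over CD133-negative cells (x axis) of the 27 gene lists (y axis, tested members in parentheses). Circles are replicate 1, squares replicate 2 and diamonds the median of the members' means over both arrays, in red for lists called higher by camera, blue for lists called lower and grey for the others. The medians run from -1.20 for mesenchymal and EMT markers to 0.95 for gastric lineage markers. Of the 13 called lists, hypoxia alone has its arrays on either side of 0, as do several lists that were not called.

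Lists of other cell types did not pass, except that endothelial and blood cell markers passed with median centring over all probes, and blood cell markers also with centring over the tested genes. Endothelial markers had a median of -0.03, with 0.05 on array 1 and -0.14 on array 2, and a mean of 0.73 over 10 members (camera adjusted p = 0.37), and the sign of the median relative to all genes changed under 3 scalings. Sox17 (4.27 ± 0.14), Vwf (3.75 ± 0.15) and Cdh5, at least 5.81-fold higher, rose. Of its members, 3 rose and 1 fell adjusted over the list alone. Fibroblast and muscle markers had a median of -0.25 over 7 members (camera adjusted p = 0.20), with Smtn at -0.99 ± 0.15 and Cnn1 at -0.88 ± 0.15. The fibroblast median relative to all genes was -0.22, and -1.02 with the deposited processed signals, with which the list did not pass either (camera adjusted p = 0.19). Blood cell markers had a median of 0.05 over 11 members (camera adjusted p = 0.69), with Csf1r at -0.87 ± 0.14 and Lyz2 at 0.34 ± 0.17, and its median relative to all genes went from 0.08 to 0.68 with median centring. Cnn1 and Csf1r were well above background in CD133-positive cells on 1 array alone, as were Twist2, Tcf7 and Sox9, so the sizes of these ratios are uncertain. No fibroblast or blood cell marker passed over all genes, and adjusted over the list alone, 3 and 1 fell.

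Cell cycle genes did not pass as a list (camera adjusted p = 0.23). Their median over 44 members was -0.18 on array 1 and 0.32 on array 2, and its sign relative to all genes changed under median centring. None passed over all genes or adjusted over the list alone. Cdc6 was at 0.99 ± 0.22 and Tyms at 0.90 ± 0.19. For p53 targets the camera adjusted p was 0.84, with Phlda3 at -2.16 ± 0.49 and Polk at -1.09 ± 0.26. For immediate-early and heat-shock genes it was 0.69, with Dusp1 at -1.38 ± 0.46 and Hspb1 at -1.34 ± 0.30. For cholesterol synthesis it was 0.89. The last 2 of these lists passed with centring over the tested genes. In these lists no gene passed over all genes or adjusted over the list alone.

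Interferon response genes did not pass as a list (camera adjusted p = 0.69), but Parp14 rose (1.71 ± 0.16) and Cxcl10 fell (-1.53 ± 0.15), while Bst2 at -1.72 ± 0.45 did not pass. Adjusted over the list alone, 1 rose and 2 fell. Growth factor genes did not pass (camera adjusted p = 0.86). Igfbp5, a growth factor binding protein, was at least 9.89-fold higher (limma adjusted p = 0.025), and it alone rose adjusted over the list alone. Pdgfc was at -1.41 ± 0.31 without passing. Housekeeping genes did not pass (camera adjusted p = 0.69), with Gusb at 1.72 ± 0.23. Over all genes none of them passed, and adjusted over the list alone, 2 rose and 2 fell.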

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

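Median centring over the tested genes was chosen after the data were seen, and the other alternatives before. Prom1 was higher in CD133-positive cells in all 15 alternatives that gave it a value, from 3.03 to 6.46, and passed in the 13 of them with a test (limma adjusted p from 0.0027 to 0.042). It was not tested with the filter for both channels, since its probe was not above background in CD133-negative cells. Leaving out either array gave 3.73 to 3.83. These alternatives choose the probe anew. With the probe kept, the Prom1 ratio relative to all genes went above this range under another choice of background or scaling. No called gene changed sign, relative to the median of all genes, under the 5 alternatives of background and scaling compared for it. For the other named genes, the 13 alternatives that tested them one by one gave 1268 values. Of these, 1100 kept their side of the threshold, 120 newly passed and 48 no longer passed. With a call in either setting, 0 changed direction. The 1100 can include values that changed direction without a call in either setting. The alternatives of the variance model and the gene test are given below as counts of calls only.

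The number of called genes was the least stable value. It was 484 with the deposited processed signals and 484 with the value table (390 higher, 94 lower, 216 shared with the 256), 412 without background correction, 545 with an offset of 16 and 624 after scaling between arrays. The last 3 kept all 256. Median centring over all probes gave 10107, of which 484 were higher, with 249 of the 256 kept. Its construction accounts for part of this, since it left the tested genes at a median of -0.70 and -0.76. Median centring over the tested genes, which removes that shift, still gave 4007 (2435 higher, 256 kept). Without a filter on background, 30 of 27667 genes were called, all among the 256, and with the dimmest probe 156. A trend in the prior variance gave 837, no moderation 0 (1506 at an unadjusted p under 0.05), and treat against a log2 fold of 0.5 gave 134. The Feature Extraction p-value, which covers technical error only, gave 3083. With no replicate block, the 4 channels as separate samples gave 1062 (542 higher, 520 lower), of which 233 were among the 256. The cause of the rest of the rise with median centring and of the other shifts was not tested. Counts from 240 to 314 came with a robust prior, the mean of probes, flagged spots kept, the filter for both channels and probes in place of genes. Leaving out saturated probes moved nothing, as none was saturated.

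The 704 genes at least 2-fold changed on both arrays became 1538 with the processed signals and 1538 with the value table, 3810 with median centring over all probes and 1073 over the tested genes. By construction the count was 1927 at 1.5-fold and 250 at 3-fold. With a single array, it was 969 to 1847, so that array 1 alone gave 969 and array 2 alone 1847. The Pearson r across genes of 0.771 became 0.744 with the processed signals and 0.744 with the value table, 0.831 with either median centring and 0.752 with the dimmest probe.

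With an estimated correlation, a form with little power at 1 residual degree of freedom, 0 of the 27 lists passed. The 13 called lists had a camera adjusted p of 0.92 there. With fry 1 passed. Its adjusted p was 0.273 for gastric, detoxification and respiratory chain, 0.371 for intestinal and mesenchymal, 0.477 for Wnt, 0.625 for TGF-beta and hypoxia, 0.452 for unfolded protein, 0.516 for extracellular matrix and ribosomal, and 0.519 for histone genes. Detoxification genes had 0.0579 with ranks and 0.0555 with the filter for both channels. The unfolded protein list had 0.0717 with the processed signals and 0.0717 with the value table, 0.0573 with an offset of 16 and 0.0741 with the dimmest probe. Ribosomal proteins had 0.212 with the processed signals and 0.212 with the value table. The cause was not tested.

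With median centring over all probes 10 lists passed, 6 of them as before. The adjusted p became 0.416 for Wnt, 0.449 for TGF-beta, 0.0850 for NF-kB, 0.867 for extracellular matrix and 0.909 for histone genes, and 0.0279 for epithelial, 0.0250 for blood cell and 0.00393 for endothelial markers. Unfolded protein (0.358) and respiratory chain genes (0.0228) reversed. Medians that reversed were -0.69 for detoxification, -0.71 for histone, -0.59 for hypoxia, -0.17 for intestinal, -0.83 for respiratory chain and -0.79 for unfolded protein genes, on a scale where all genes had moved down. Relative to all genes, the respiratory chain and unfolded protein lists alone among the 13 changed sign. Centring over the tested genes gave 0.0583 for Wnt, 0.475 for detoxification, hypoxia and histone, 0.0944 for extracellular matrix, 0.0185 for immediate-early, 0.0196 for cholesterol and 0.0217 for blood cell genes. There, unfolded protein (0.475, median -0.060) and respiratory chain genes (0.237, median -0.10) reversed. The cause was not tested. With a single array the hypoxia median was -0.11 to 0.71, so its direction rests on array 1.

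Among tested genes, 177 were above background in CD133-negative cells on neither array and 441 in CD133-positive cells on neither array, and their ratios depend on the offset. Among the called genes 10 were of the first kind and 0 of the second.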

Other observations

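The tests chosen after the results were seen were those on carried-over cells, on endothelial cells, on fibroblasts and on gene clusters of chromosomes 13 and 19, as well as the 8 gene groups at the end. The other tests were written before. The limit for a shift of a chromosome was set before any chromosome was looked at, but 20 chromosomes were looked at, and the shuffling and the statistic that takes the smaller of both arrays came after.

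Genes lower in CD133-positive cells had lower ratios on array 2 than on array 1. Over 730 genes with a mean of at least 2-fold lower and the same direction on both arrays, array 2 minus array 1 had a median of -0.83, and 93.8% were lower on array 2. Over 540 genes higher by the same rule the median was 0.04. If CD133-negative cells had been carried into the CD133-positive fraction of replicate 1, the lower genes would give a share of 30.1%, which gene by gene predicts a median of 0.33 for the higher genes. The observed 0.037 lies below that by 0.29 (95% bootstrap interval over genes 0.23 to 0.36). Without an offset of the genes, this argues against carried-over cells as the whole cause. Genes are not independent replicates, so the interval does not measure the spread between replicates. An earlier form of the test set the prediction at 0.52, which holds in the limit of very high ratios alone. The 10 spiked-in controls were all lower on array 2, by 0.23 to 0.42, and an offset of that size on the genes would raise the higher genes to between 0.27 and 0.46. With the smallest fall corrected on array 1 or 2, the share solved anew predicted 0.22 or 0.29 for the higher genes, against 0.27. With the largest fall it predicted 0.14 or 0.24, against 0.46. The offset would also raise the median of all genes to between 0.17 and 0.37, where carried-over cells predict at most 0.07. Loess centres all genes on both arrays, so this gap follows from the offset itself and cannot decide. Whether the offset applies to the genes is not known, so with an offset near the smallest fall carried-over cells stay open. What caused the offset of the controls was not tested. A test tried first, which compared the share solved from moderately and from deeply lower genes (28.5% and 33.5%), had been undecided. Over the lower genes the median was -0.86 with median centring in place of loess, which argues against loess on array 1. Without background correction it was -0.83, which argues against that correction on array 1. It was -1.12 with the deposited processed signals, which carry a background subtraction and dye normalisation of their own. With an offset of 16 it was -1.04, so its size depends on how background is handled. Background left in Cy3 of array 1 is argued against by a median of -0.80 over the brightest of 3 brightness groups of the lower genes, against -0.78 over the dimmest. In size these exceed the largest fall of a control, 0.42. A biological difference between the replicates stays open and was not tested. The labels do not say whether they were separate cultures.

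Some genes listed as markers of other cell types moved with the fractions. Endothelial cells sorted with the CD133-positive fraction would explain Sox17, Vwf and Cdh5, but of 11 other endothelial transcripts, 3 were well above background in CD133-positive cells on both arrays and 0 were at least 2-fold higher on both arrays. Pecam1, Kdr and Tek were not well above background in either fraction on any array. Fibroblasts in the CD133-negative fraction would explain lower mesenchymal genes, but of 10 abundant fibroblast transcripts, 1 (Col1a2) was well above background in CD133-negative cells on both arrays, and 0 were at least 2-fold lower on both arrays. Sox17 is also a transcription factor of endoderm. The cells were a cultured line sorted on CD133 alone, which would not remove other cells with CD133. A difference of expression within the GIF-5 cells stays open as a hypothesis.

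Genes of chromosomes 13 and 19 were lower as a set in CD133-positive cells. Relative to the other autosomes, the median log2 ratio was -0.21 on array 1 and -0.21 on array 2 for the 559 genes of chromosome 13, and -0.23 and -0.38 for the 554 of chromosome 19. Chromosomes 18 (0.16 and 0.24) and 7 (0.16 and 0.16) lay above the median of the other autosomes on both arrays. The largest shift reached in the same direction on both arrays was 0.230. Of 1000 shufflings of genes over chromosomes 0 gave as much, the highest being 0.063. Beyond 0.063 on both arrays were also chromosomes 4 (-0.12 and -0.17), 6 (0.08 and 0.14), 10 (0.12 and 0.17) and 15 (-0.065 and -0.10). So were chromosomes 7 and 18. The shuffling, which treats genes as independent, therefore does not set chromosomes 13 and 19 apart from these autosomes. Chromosome X, which was left out of the shuffling, was at -0.14 on array 1 and -0.09 on array 2 relative to the autosomes. Genes are not independent replicates, and neighbouring genes can be regulated together. Normalisation is argued against, since with the processed signals or median centring the medians of both chromosomes were at most -0.241 on either array. In 3 parts of equal gene number, chromosome 19 had a highest part median of -0.179, which argues against a few clusters. For chromosome 13 the highest part median was -0.0774, too near 0 to exclude clusters and too far from it to need them, so clusters and a shift of the whole chromosome cannot be told apart there. These parts were first tested for both chromosomes together, which left it undecided. On chromosome 2 the first part was at -0.24 and -0.25 and the last at 0.12 and 0.22. A candidate explanation is a copy number difference between subclones of the line that differ in CD133. DNA was not measured, and regulation along a chromosome stays open.

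The following gene groups were chosen after the called genes had been seen, so their counts are descriptions. Of 22 liver-type plasma protein genes tested, 11 rose, among them Alb (2.75 ± 0.14) and Afm (3.94 ± 0.14), and C3 and Cp (-1.67 ± 0.16) fell. Of 16 genes of alcohol, sulfate and glucuronide metabolism with Cyp2c and Cyp2d genes, 10 rose, among them Adh1 (4.49 ± 0.14). Of 12 endoderm transcription factors, Sox17 and Isx rose. Of 8 basement membrane genes, Col4a1, Col4a2 and Lamb1 rose. Serpinh1 (3.03 ± 0.48), Nid2 (at least 6.38-fold higher) and Lamc1 (0.80 ± 0.15) were higher without passing. Serpinh1 was well above background in CD133-negative cells on 1 array alone. Sparc (-1.27 ± 0.17) and Nid1 (-1.16 ± 0.14) were lower without passing. Of 3 Reg genes 1 rose, Reg3g, and Reg1, which was well above background in CD133-negative cells on 1 array alone, did not pass. Of 4 Bex genes, Bex2 (4.66 ± 0.15) and Bex4 (4.05 ± 0.14) rose. Of 13 genes named S100, S100g rose and S100a4 fell. Of 15 Hox genes 0 passed, and 3 were at least 2-fold lower on both arrays.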
